A study of Mus musculus with 12 samples.

How the data were processed

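Gene expression was measured by RNA sequencing in 12 libraries, 3 for each of 4 groups of sorted mouse dendritic cells (DCs). Per the labels' protocols, RNA was extracted with a DNase step, TruSeq RNA libraries were made, and single-end reads were sequenced on a NextSeq. The authors deposited raw counts for 57009 Ensembl gene identifiers, with no normalization: the values are whole numbers that sum to between 13903574 and 21861156 per library. A second deposited table gave each library a batch number from 1 to 3, equal to the replicate number in 12 of 12 libraries. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool, the strand setting and the annotation release are not given in the sources used here. Symbols and coordinates came from GENCODE M21 (GRCm38) by match of the identifier, for 52028 identifiers. The other 4981 kept their identifier and held 0.763% of counts. Of all identifiers 31565 had 0 counts in every library, and 66 shared a symbol with another.

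Genes with few counts were left out with filterByExpr (minimum count 10, minimum total 15), which left 14413. Counts were scaled by the trimmed mean of M values (TMM) and fitted over the 12 libraries with 1 mean per group in edgeR 4.0.16 (R 4.3.3), with robust quasi-likelihood dispersions. Comparisons were of AlloTem with SynTem, with DC only and with LPS, and of LPS and SynTem with DC only. P-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and a gene was called at an adjusted p under 0.05. Standard errors are the log2 fold change divided by the square root of the F statistic. Levels are given in CPM (counts scaled to a common, TMM-adjusted library total), and ratios within a batch were taken after adding 0.5 CPM. Principal components were taken from log2 CPM with a prior count of 2.

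Gene lists were written before the files were seen: 32 lists with 597 distinct genes (19 pathways, 11 cell types, 2 of quality). Each list with at least 3 tested members, 31 in all, was tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, again with the correlation estimated per list, and with fry. P-values were adjusted over the lists of a comparison. Members were also adjusted over their list alone.

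The comparisons, the test, the threshold, the lists and the rule for naming genes were chosen before the data were examined. The rule named, per comparison, the 10 largest rises and 5 largest falls among called genes that had a symbol other than a predicted one, a mean of at least 5 CPM and no overlap between the replicates of the groups. It also named 19 genes chosen in advance (such as Il1b, Il6, Tnf, Cd80, Cxcl9 and Cd3e), and for each list up to 3 called members with the largest change (mean of at least 1 CPM), or the member with the smallest p where none was called. Among those chosen in advance, Ifnb1 and Il2 had too few counts to be tested.

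Alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, limma voom, no filter, a filter at a mean of 5 CPM, a fold threshold, only the 6 libraries compared, the batch number as a block, and leaving out each library in turn. Added after the files were seen were thinning each library to the smallest total, the level of Y-linked transcripts as a covariate, and leaving out DC only 2 and SynTem 2 with and without the block. For the block and the ratios within a batch, the batch numbers were taken to pair the libraries because the deposited table gives them as batches. The main fit held no batch term, as chosen before the data were examined, so its p-values do not use this pairing. As a check, deviations from the group means were correlated between libraries: the median was 0.245 over 18 pairs with the same number (12 of them above 0.1, range -0.24 to 0.63) and -0.175 over other pairs. Of the 12 libraries 10 correlated best with their own number; DC only 2 and SynTem 2 did not.

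The scripts were tested on counts simulated from these libraries with 200 genes changed. For AlloTem against SynTem, with 14111 genes, edgeR recovered 47 of 100 genes changed 2-fold and 80 of 100 changed 4-fold, with 1 false call in 128. For LPS against DC only, with 14116 genes, it recovered 49 and 83 of 100, with 3 false calls in 135, where DESeq2 made 30 false calls in 188. Changes of these sizes were thus missed in part at this depth and spread, and smaller ones could be missed more often. The simulated counts were drawn gene by gene around group means, without batches and without correlation between genes. Larger changes could thus be missed in the real libraries too.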

Results

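RNA was sequenced from mouse splenic dendritic cells (DCs), the antigen-presenting cells that start T cell responses, after 3 h of culture under 4 conditions with 3 libraries each, 12 libraries in all. The DCs came from C57BL/6 mice injected with B16 melanoma cells that secreted Flt3 ligand, a growth factor that expands DCs, and were enriched from the spleen by removing lymphocytes and macrophages with beads. They were cultured alone (the DC only group) or with lipopolysaccharide (the LPS group), a bacterial cell wall component sensed by a Toll-like receptor. The 2 other groups were cultured with syngeneic effector memory T cells (the SynTem group), or with alloantigen-specific memory T cells derived from BALB/c mice (the AlloTem group). DCs were then sorted on CD11b and CD11c, and the share of T cell RNA left in each library was not estimated. Total counts were 16323673, 17977289 and 19461531 in DC only libraries 1 to 3 and 16587165, 17459890 and 17472400 in LPS. They were 13903574, 14659362 and 15982118 in SynTem and 21861156, 21555110 and 20055002 in AlloTem. Of 57009 gene identifiers, 14413 had enough counts to be tested. Each library carried a deposited batch number, from 1 to 3, equal to its replicate number in 12 of 12 libraries, with no statement of what a batch was. The labels do not say whether replicates were separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. DC only libraries 1 and 2 were the closest pair within a group (chi-square per degree of freedom 6.14, Spearman correlation 0.9931, against 26.45 to 80.69 in the 11 other pairs), still differed beyond sampling noise and were counted as 2 replicates.

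Transcripts of T cells and of the sex chromosomes showed what else differed between libraries. The summed level of 23 T cell markers, among them the T cell receptor chains, was 330.7, 799.9 and 645.5 CPM in SynTem libraries 1 to 3. It was 352.3, 206.9 and 180.2 CPM in AlloTem, 79.1 to 124.6 CPM in DC only and 85.8 to 215.7 CPM in LPS. Xist, the RNA that silences an X chromosome in female cells, was between 610.0 and 1188 CPM in the 7 libraries of batches 1 and 2 other than SynTem 2, and 137.6 to 145.7 CPM in batch 3 of DC only, LPS and AlloTem. Y-linked transcripts (Ddx3y, Eif2s3y, Kdm5d and Uty) summed to 203.8 to 219.6 CPM in those same 3 libraries of batch 3, and to 0 to 10.3 CPM in the 7 others. Those 3 libraries of batch 3 thus held both. So did SynTem 2 (312.1 CPM of Xist, 175.1 CPM of Y-linked transcripts) and SynTem 3 (455.1 and 130.9 CPM), with more Xist and fewer Y-linked transcripts. In a principal component analysis the first component took 26.9% of the variance and was negative for DC only 3, LPS 3, SynTem 2, SynTem 3 and AlloTem 3 and positive for the 7 other libraries. The main axis followed these transcripts and not the 4 conditions.

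**Figure D1:**
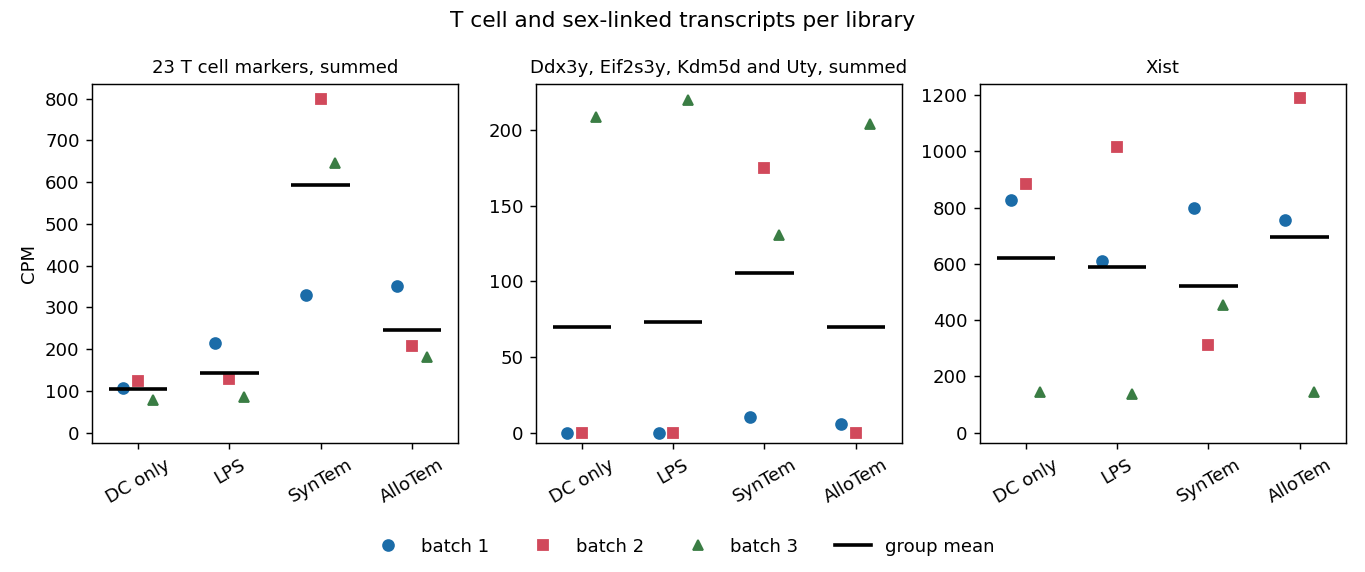
Summed CPM of 23 T cell markers, summed CPM of 4 Y-linked genes and CPM of Xist (linear axes) in each of the 12 libraries, by group, with the batch given by the symbol. SynTem 2 held 799.9 CPM of T cell markers and 175.1 CPM of Y-linked transcripts, while the other batch 2 libraries held 0 CPM of Y-linked transcripts.

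The comparison of AlloTem with SynTem set DCs cultured with alloantigen-specific memory T cells beside DCs cultured with syngeneic memory T cells. The T cells of these groups also differed in strain. An effect of T cell strain therefore cannot be told apart from recognition of the DCs as foreign. Ccl17, a chemokine that draws T cells bearing CCR4, had the largest fold among the genes that rose: 109.6 ± 69.7 CPM in AlloTem against 1.59 ± 0.997 CPM in SynTem (SD, n = 3 each). This was a 67.1-fold difference (log2 6.07 ± 0.72 SE, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0126). Irf4, a transcription factor of conventional type 2 DCs, rose 3.55-fold from 108.0 ± 11.4 to 383.6 ± 83.7 CPM (edgeR adjusted p = 0.00276). Gprc5c, an orphan G protein-coupled receptor, rose 8.06-fold from 9.56 ± 2.99 to 77.3 ± 21.7 CPM (edgeR adjusted p = 0.00276). Ier3, an early gene that restrains cell death, rose 6.6-fold from 41.5 ± 11.5 to 274.3 ± 24.9 CPM (edgeR adjusted p = 0.00456). In coordinates of the mouse build GRCm38, Ccl17 (ENSMUSG00000031780) lies on chromosome 8 from 94810453 to 94812036 and Irf4 (ENSMUSG00000021356) on chromosome 13 from 30749226 to 30766976. Gprc5c (ENSMUSG00000051043) lies on chromosome 11 from 114851152 to 114872617 and Ier3 (ENSMUSG00000003541) on chromosome 17 from 35821684 to 35822923.

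In all, 22 genes rose and 2 fell in AlloTem relative to SynTem (edgeR quasi-likelihood test, adjusted p under 0.05, 1381 genes at an unadjusted p under 0.05), 20 of the 22 by at least 2-fold. The zinc transporter Slc30a4, E-cadherin (Cdh1) and the heparan sulfate proteoglycan Sdc4 rose by 2.79 ± 0.30, 2.99 ± 0.39 and 2.82 ± 0.41 on the log2 scale (edgeR adjusted p = 0.00623, 0.0137 and 0.0268). The tight junction protein Cldn1, the ubiquitin ligase Rnf24 and the transcription factor Nfil3 rose by 2.27 ± 0.31, 1.97 ± 0.28 and 1.65 ± 0.21 (edgeR adjusted p = 0.0167, 0.0198 and 0.0126). The kinase Pim3 and the glucose transporter Slc2a1 rose by 1.11 ± 0.15 and 1.04 ± 0.16 (edgeR adjusted p = 0.0137 and 0.0283). These 12 genes were higher in AlloTem in 3 of 3 batches. The deviations of SynTem 2 from its group mean correlated at 0.44 with the batch 3 libraries of the other groups and at -0.11 with those of batch 2. Ratios within batch 2 that use SynTem 2, here and below, may thus compare different DC sources. SynTem 3 correlated at only 0.09 with the batch 3 libraries of the other groups. DC only 2 correlated at 0.25 with those of batch 1 and at -0.02 with those of batch 2. Ratios within a batch that use SynTem 3 or DC only 2 thus also rest on a doubtful pairing. For Ccl17 the log2 ratios within batches 1, 2 and 3 were 6.16, 6.39 and 4.48, for Irf4 1.83, 1.97 and 1.62, and for Ier3 3.32, 2.38 and 2.54. The genes that fell, named after their values were seen, were Nrn1 (log2 -6.60 ± 1.08, edgeR adjusted p = 0.0484) and F630028O10Rik (-1.87 ± 0.27, edgeR adjusted p = 0.0198). Part of the exons of Rnf24 (16.5% of bases) overlaps Pank2 on the other strand, and whether counting used strand is not given.

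The count depended on single libraries and on the batch term. With the batch as a block 78 genes passed (67 higher, 11 lower), including all 24. Without SynTem 1, SynTem 2 or SynTem 3 the count was 11, 3 and 11, and without AlloTem 3 it was 47. Irf4, Gprc5c and Ier3 passed in each of the 6 fits that left out a library. Without SynTem 2 the adjusted p of Ccl17 was 0.101, that of Slc30a4 0.0640 and that of Sdc4 0.163, with the direction kept for all 24 genes. In a fit of the 6 libraries alone 0 genes passed (edgeR, 989 at an unadjusted p under 0.05, smallest adjusted p = 0.0786), while over the 12 libraries DESeq2 called 318 and limma voom 26. Irf4 and Gprc5c alone passed when DC only 2 and SynTem 2 were both left out.

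**Figure D2:**
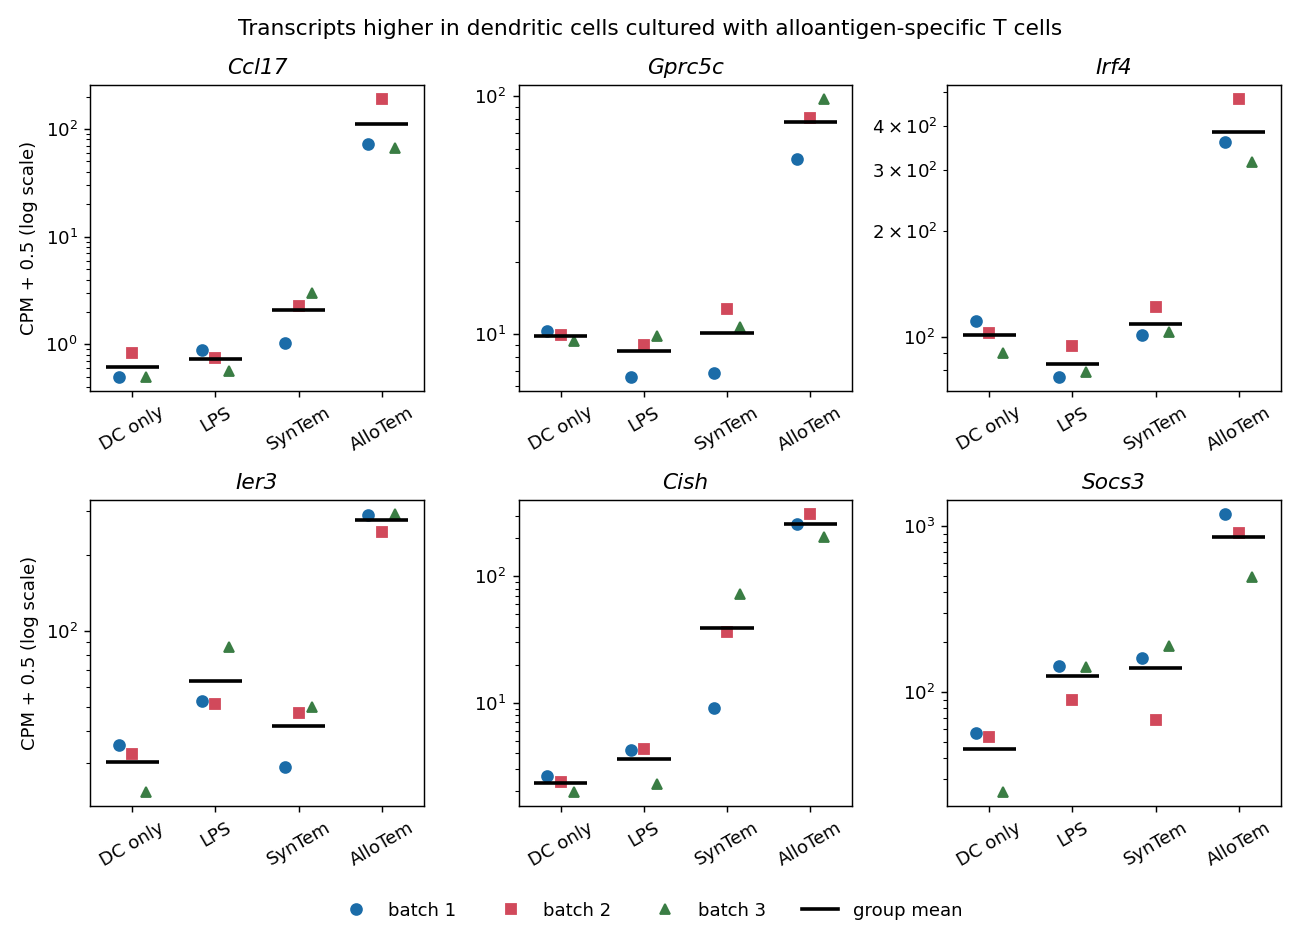
CPM plus 0.5 (log axis) of Ccl17, Gprc5c, Irf4, Ier3, Cish and Socs3 in the 12 libraries, by group, with the batch given by the symbol and the group mean as a black line. Irf4 lay between 315.6 and 477.1 CPM in AlloTem and between 100.7 and 121.2 CPM in SynTem.

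Of 31 gene lists tested, 14 were higher and 1 lower in AlloTem than in SynTem (camera with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the lists). The list of STAT6 response genes, which interleukin signals of helper T cells induce, had 13 of 15 tested members positive with a median log2 change of 1.71 (camera adjusted p = 6.39e-11, adjusted p = 0.0224 with an estimated correlation). Ccl17, Cdh1 and Irf4 rose among its members, and 9 members rose when adjusted over the list alone; the medians within batches were 1.25, 1.98 and 1.07. It was the one list of the 31 that passed with an estimated correlation. STAT5 response genes had 13 of 16 members positive and a median of 1.05 (camera adjusted p = 8.2e-07, adjusted p = 0.243 with an estimated correlation): Nfil3 and Pim3 rose, while adjusted over the list alone 8 rose and 2 fell. Of the 26 immediate early genes 25 were positive, Ier3 rose, and 9 rose adjusted over the list alone (median 0.83, camera adjusted p = 6.39e-11, adjusted p = 0.287 with an estimated correlation).

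Lists of inflammatory genes were also higher in AlloTem, while most of their single members did not pass. Inflammatory cytokines had 14 of 16 members positive and a median of 0.91 (camera adjusted p = 2.98e-07, adjusted p = 0.287 with an estimated correlation), with batch medians of 1.26, 2.63 and 0.02. Of them 0 passed over all genes (edgeR; 5 at an unadjusted p under 0.05, 3 by DESeq2, 1 by voom) and 4 rose adjusted over the list alone. Il6 was 33.2 ± 9.37 CPM in AlloTem and 5.57 ± 3.36 CPM in SynTem (log2 2.57 ± 0.50, edgeR adjusted p = 0.0858). Il1b was 852.0 ± 346 and 208.1 ± 201 CPM (log2 2.03 ± 0.67, edgeR adjusted p = 0.331). For Osm, Il12b and Tnf the log2 differences were 2.25, 1.32 and 0.63 (edgeR adjusted p = 0.0858, 0.628 and 0.801). DC maturation and costimulation genes had 25 of 26 members positive and a median of 1.08 (camera adjusted p = 9.05e-11, adjusted p = 0.287 with an estimated correlation). Of these 0 passed over all genes (edgeR; 13 at an unadjusted p under 0.05, 5 by DESeq2, 0 by voom) and 6 adjusted over the list alone. Cd40 and Cd80, which deliver costimulation, differed by 1.64 ± 0.52 and 1.63 ± 0.38 (edgeR adjusted p = 0.316 and 0.145), Cd86 by 0.57 and Ccr7 by 0.41. NF-kB targets had 26 of 29 members positive, a median of 0.69 and 4 members that rose adjusted over the list alone (camera adjusted p = 2.8e-10, adjusted p = 0.372 with an estimated correlation). Of the 15 chemokines Ccl17 rose, 3 rose adjusted over the list alone, and the list median was 0.44 (camera adjusted p = 0.00142, adjusted p = 0.377 with an estimated correlation) but -0.38 within batch 3.

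Metabolic and antigen presentation lists moved little. Medians were 0.12 for oxidative phosphorylation, 0.28 for cholesterol synthesis, 0.10 for heat shock and 0.26 for MHC class II presentation (camera adjusted p = 0.000152, 0.0139, 0.0374 and 0.0377; adjusted p = 0.432, 0.616, 0.287 and 0.616 with an estimated correlation). The median was -0.03 within batch 3 for oxidative phosphorylation and -0.14 within batch 1 for MHC class II presentation. All but oxidative phosphorylation lost their call without SynTem 3 (adjusted p = 0.0786, 0.463 and 0.0645 for heat shock, MHC class II presentation and cholesterol synthesis). MHC class II presentation lost it also without SynTem 2 (0.0734), heat shock without AlloTem 1 (0.0775), and cholesterol synthesis and MHC class II presentation without AlloTem 2 (0.655 and 0.666). With the level of Y-linked transcripts as a covariate cholesterol synthesis and MHC class II presentation did not pass (0.0996 and 0.212). Interferon lists did not pass: type I interferon response had camera adjusted p = 0.998 and batch medians of -0.32, 2.50 and -2.18, and interferon gamma response had camera adjusted p = 0.0916 and batch medians of -0.21, 0.76 and -1.63. Without AlloTem 2 both lists passed as lower in AlloTem (0.00797 and 0.000441), without SynTem 2 the interferon gamma list did so (0.00854), and without AlloTem 3 the type I list passed as higher (0.0325). The fits that left out a library also left the batches unequal between the groups. With the Y-linked covariate both lists passed as lower (camera adjusted p = 7.53e-08 and 2.83e-05). Cxcl9 and Cxcl10, chemokines induced by interferon, differed by 0.18 ± 1.28 and -0.96 ± 1.27 (edgeR adjusted p = 0.978 and 0.861), with Cxcl10 at log2 4.37 in batch 2 and -4.24 in batch 3.

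Some markers of other cells also differed between AlloTem and SynTem, in either direction. T cell markers were lower in AlloTem for 22 of 23 genes, with a median of -1.64 (camera adjusted p = 9.05e-11, adjusted p = 0.287 with an estimated correlation) and batch medians of 0.12, -2.71 and -2.14. Of them 10 fell adjusted over the list alone. The T cell receptor component Cd3e was 4.47 ± 1.87 CPM in AlloTem and 29.7 ± 18.6 CPM in SynTem (log2 -2.73 ± 0.67, edgeR adjusted p = 0.159). Cytokines of activated T cells went the other way, with 8 of 10 positive and a median of 1.29 (camera adjusted p = 0.00765, adjusted p = 0.372 with an estimated correlation). Their batch medians were 2.22, 1.25 and -0.20, and they were not called with the batch block (adjusted p = 0.0608), without AlloTem 1 (0.0765) or with the Y-linked covariate (0.0731). Adjusted over the list alone 4 rose and 1 fell. Markers of plasmacytoid DCs had a median of 0.48 (camera adjusted p = 4.98e-05, adjusted p = 0.287 with an estimated correlation). Markers of erythroid cells and platelets had a median of 0.98 (camera adjusted p = 0.0475, adjusted p = 0.448 with an estimated correlation). The adjusted p was 0.0564 under the block and between 0.0581 and 0.341 without SynTem 1, SynTem 2, SynTem 3, AlloTem 1 or AlloTem 3.

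**Figure D3:**
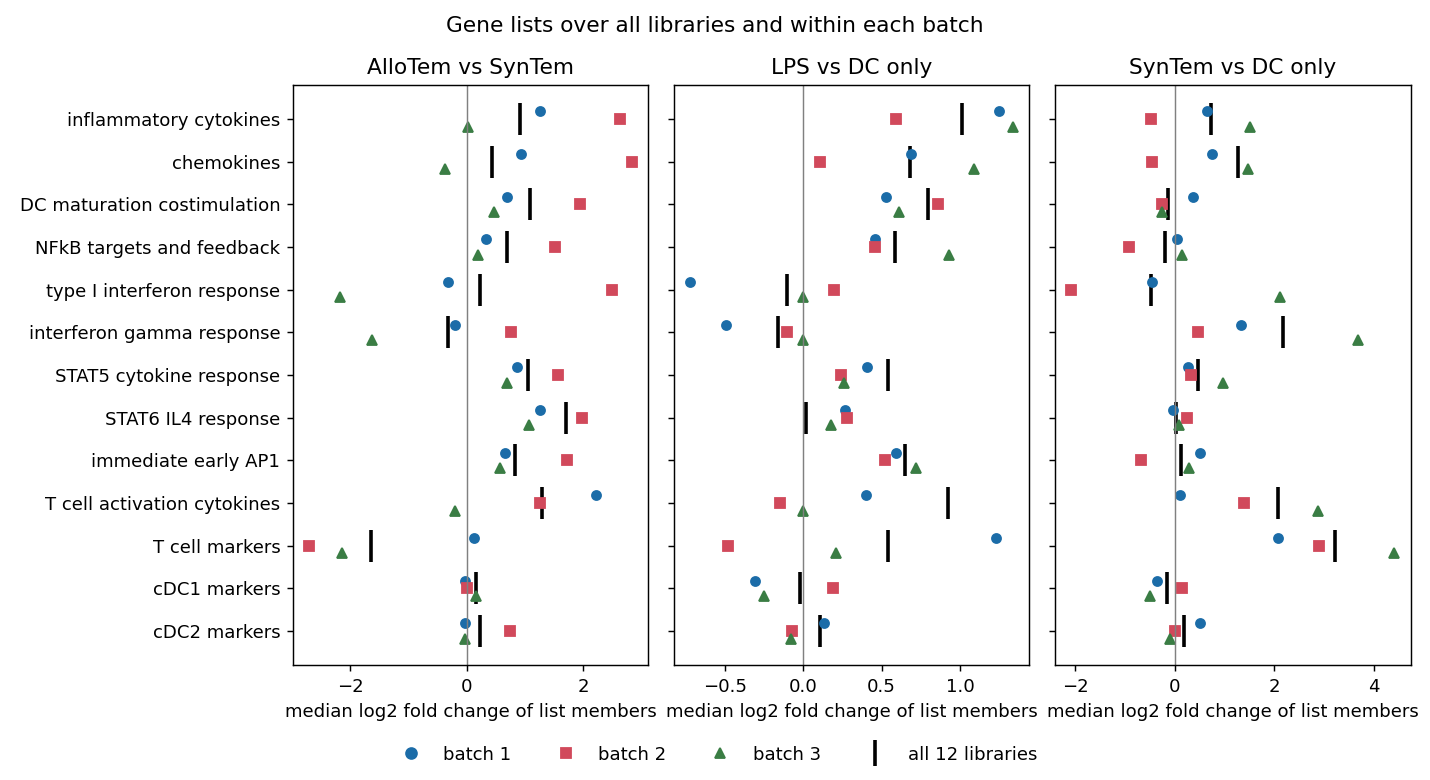
Median log2 fold change over the tested members of 13 gene lists for AlloTem against SynTem, LPS against DC only and SynTem against DC only (bars, edgeR over the 12 libraries), with the medians of the log2 ratios within each batch as symbols. The horizontal scales differ between panels. For STAT6 response genes in AlloTem against SynTem the bar is at 1.71 and the 3 batches at 1.25, 1.98 and 1.07, whereas for inflammatory cytokines the batches range from 0.02 to 2.63.

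The LPS comparison asked how the same DCs respond to an innate stimulus over 3 h. Inflammatory genes were higher with LPS in each batch, although by edgeR no single gene passed over all genes. Il1b was 715.3 ± 271 CPM with LPS and 236.6 ± 106 CPM in DC only (3.02-fold), Il6 14.6 ± 5.68 and 4.0 ± 1.73 CPM (3.67-fold, SD, n = 3 each). Il12b was 19.9 ± 8.94 and 4.12 ± 0.483 CPM (4.84-fold) and Tnf 193.2 ± 72.1 and 76.4 ± 40.3 CPM (2.53-fold). All 4 genes were higher in 3 of 3 batches, of which batch 2 rests on DC only 2, whose pairing is in doubt. The neutrophil chemokine Cxcl2 was 22.4 ± 12.3 against 1.59 ± 0.249 CPM (14.1-fold, log2 3.81 ± 0.78), and Ccr7, the receptor that guides DCs to lymph nodes, 371.8 ± 144 against 152.6 ± 9.38 CPM (2.44-fold). Over all genes the adjusted p was 0.999 for each of these 6 genes (edgeR quasi-likelihood test), whereas DESeq2 called Cxcl2 (DESeq2 adjusted p = 8.69e-05). In coordinates of GRCm38, Il1b (ENSMUSG00000027398) lies on chromosome 2 from 129364570 to 129371139.

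By edgeR 0 of 14413 genes passed (smallest adjusted p = 0.787), with 531 at an unadjusted p under 0.05, of which 324 were higher with LPS. DESeq2 called 10 genes, among them Cxcl2, Il1a and Nr4a2 (DESeq2 adjusted p = 8.69e-05, 0.00942 and 0.00308), limma voom 0 and the fit with the batch as a block 0 (801 at an unadjusted p under 0.05). Without DC only 2 a single gene passed, the ribosomal pseudogene Rps12-ps3 (edgeR adjusted p = 0.00366), named after its values were seen. In data simulated from these libraries edgeR recovered 49 of 100 genes changed 2-fold and 83 of 100 changed 4-fold in this comparison. Those counts were drawn without batches or correlation between genes. In the real libraries Cxcl2 and Il12b, both changed over 4-fold, did not pass by edgeR, so recovery there may be lower.

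As lists the inflammatory genes did pass. All 29 NF-kB targets were positive, with a median of 0.58 and batch medians of 0.46, 0.46 and 0.93 (camera adjusted p = 1.05e-12, adjusted p = 0.317 with an estimated correlation). Immediate early genes were positive for 25 of 26 members, with 2 that rose adjusted over the list alone, and a median of 0.65 (camera adjusted p = 1.12e-12, adjusted p = 0.317 with an estimated correlation). DC maturation genes had a median of 0.80 (24 of 26 positive, camera adjusted p = 2.7e-09, adjusted p = 0.317 with an estimated correlation). Inflammatory cytokines had 14 of 16 positive (camera adjusted p = 5.4e-08, adjusted p = 0.286 with an estimated correlation), and adjusted over the list alone Il1a and Il6 rose (adjusted p = 0.005 and 0.0249, edgeR). Chemokines had 13 of 15 positive (camera adjusted p = 9.85e-05, adjusted p = 0.317 with an estimated correlation), and adjusted over the list alone Cxcl2 and Cxcl1 rose (adjusted p = 0.0085 and 0.0441, edgeR). Cxcl1 had 0 counts in the 3 DC only libraries and 29 with LPS, at least 10.1-fold higher against a floor of 3 counts over the group. STAT5 response genes had a median of 0.54, and 4 rose adjusted over the list alone (camera adjusted p = 1.8e-05, adjusted p = 0.262 with an estimated correlation). Type I interferon and interferon gamma response genes did not pass (camera adjusted p = 0.532 and 0.347). Without DC only 3 they passed as lower with LPS (1.1e-05 and 0.000951), and without LPS 2 likewise (0.000143 and 0.0149). Without LPS 3 the type I list passed as higher (0.0252). These fits left the batches unequal between the groups. The type I list summed to 784.58 CPM in DC only 3 against 3055.11 and 3130.09 CPM in DC only 1 and 2. Its batch medians were -0.72, 0.20 and 0, so in these fits a batch difference cannot be told apart from an effect of LPS.

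Some markers of other cells also differed with LPS, by amounts that varied between batches. Neutrophil markers had batch medians of 3.10, 1.11 and 0.11 (camera adjusted p = 0.000225, adjusted p = 0.622 with an estimated correlation; 0.110 without LPS 1). Erythroid and platelet markers had 3.03, 0.63 and 0.17 (camera adjusted p = 2.58e-05, adjusted p = 0.262 with an estimated correlation). T cell markers had batch medians of 1.23, -0.48 and 0.21 (camera adjusted p = 0.0254, adjusted p = 0.891 with an estimated correlation; 0.743 without LPS 1 and 0.499 without DC only 3). Plasmacytoid DC markers were lower, with batch medians of -0.88, -0.47 and 0.19 (camera adjusted p = 0.000447, adjusted p = 0.317 with an estimated correlation; 0.0519 without LPS 1). Heat shock genes (median 0.09) and TNF receptor and CD40 signalling genes (0.18) also passed (camera adjusted p = 0.00716 and 0.0356; adjusted p = 0.262 and 0.737 with an estimated correlation). The first did not pass without LPS 1 (0.0555) and the second did not without LPS 1 (0.465) or DC only 3 (0.349). Natural killer cell markers had batch medians of 1.65, -2.96 and 0.14 and did not pass (camera adjusted p = 0.667), but passed as lower with LPS without LPS 1 (0.000701) or DC only 3 (0.0221). Monocyte and macrophage markers passed with the batch block (0.0388) and not without it (0.0728), and in fits without the block that left out DC only 2 (0.0218) or LPS 3 (0.00408).

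**Figure D4:**
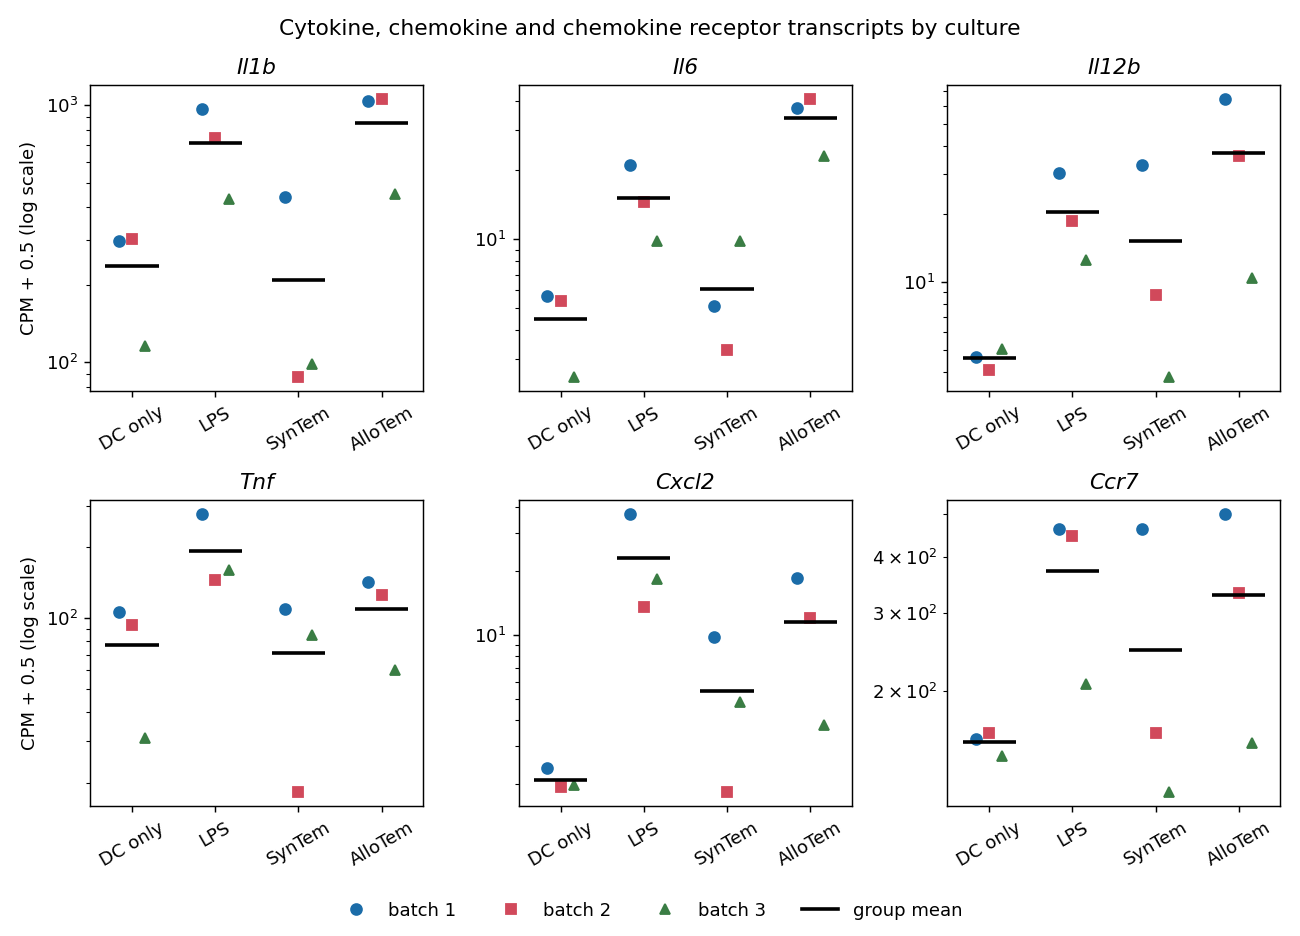
CPM plus 0.5 (log axis) of Il1b, Il6, Il12b, Tnf, Cxcl2 and Ccr7 in the 12 libraries, by group, with the batch given by the symbol and the group mean as a black line. Mean Il1b was 715.3 CPM with LPS, 852.0 CPM in AlloTem, 208.1 CPM in SynTem and 236.6 CPM in DC only.

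Set against DCs cultured alone, AlloTem libraries showed a broad change. In them 194 genes rose and 59 fell (edgeR quasi-likelihood test, adjusted p under 0.05). T cell genes such as Cd3e and Cd40lg were among those that rose. How much of the change lay in the DCs and how much in T cell RNA was not estimated. Inhibitors of cytokine signalling rose: Cish from 1.83 ± 0.333 to 258.1 ± 51.9 CPM (log2 7.15 ± 0.74, edgeR adjusted p = 0.00214) and Socs3 from 44.7 ± 17.5 to 862.6 ± 347 CPM (log2 4.27 ± 0.51, edgeR adjusted p = 0.00438). Socs1 rose by 4.14 ± 0.79 (edgeR adjusted p = 0.0293, 0.0644 with the batch block). Ccl17 rose by 9.85 ± 0.94 and Irf4 by 1.93 ± 0.16 (edgeR adjusted p = 0.00171 and 0.00096). Ccl17 had 6 counts over the 3 DC only libraries, so its fold is imprecise: leaving out a library gave log2 changes from 9.19 to 13.93. The cytokines Lif, Il1a, Osm and Il6 rose by 5.59 ± 1.01, 5.06 ± 0.70, 3.90 ± 0.47 and 3.06 ± 0.51 (edgeR adjusted p = 0.0241, 0.00647, 0.00438 and 0.0178). The inhibitory ligands Cd274 and Pdcd1lg2, which bind PD1 on T cells, rose by 3.08 ± 0.62 and 2.62 ± 0.45 (edgeR adjusted p = 0.0359 and 0.0191). Cish (ENSMUSG00000032578) lies on chromosome 9 from 107296026 to 107302784 of GRCm38.

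Further genes that rose were the mast cell protease Cpa3, the growth factor Hbegf, the transcriptional regulators Id1 and Egr2 and the matrix protein Ecm1. Their log2 changes were 6.18 ± 1.04, 5.58 ± 0.90, 5.56 ± 0.58, 4.02 ± 0.60 and 4.75 ± 0.53 (edgeR adjusted p = 0.0191, 0.0159, 0.00209, 0.012 and 0.00266). Of the genes that the naming rule allowed, which leaves out predicted symbols, the largest falls were those of the potassium channel subunit Kcne3 (-1.76 ± 0.29), the lysophosphatidic acid receptor Lpar6 (-1.44 ± 0.29), Snx22 (-1.43 ± 0.29), the kinase Sgk1 (-1.30 ± 0.24) and Tifab (-1.22 ± 0.15). In this order the edgeR adjusted p was 0.0164, 0.0328, 0.0353, 0.0267 and 0.00438. Il1b, Il12b, Cd80 and Csf2 were higher by 1.85 ± 0.66, 3.14 ± 0.85, 1.49 ± 0.38 and 4.83 ± 1.08 without passing (edgeR adjusted p = 0.259, 0.122, 0.0976 and 0.0528); without AlloTem 3 Cd80 and Csf2 passed (0.026 and 0.0344). Exons of Cd274, Lpar6 and Snx22 overlap genes on the other strand in 14.1%, 7.6% and 28.5% of bases.

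Lists placed these genes in groups, of which 13 of 31 were higher in AlloTem than in DC only. STAT5 response genes had 10 that rose, led by Cish, Socs3 and Socs1, and 1 that fell, with a median of 1.86 (camera adjusted p = 1.65e-11, adjusted p = 0.0502 with an estimated correlation). Adjusted over the list alone 11 rose and 2 fell. STAT6 response genes had 5 that rose, led by Ccl17, Egr2 and Cdh1, and 10 adjusted over the list alone (median 1.88, camera adjusted p = 4.58e-11, adjusted p = 0.0242 with an estimated correlation). Interferon gamma response genes were positive for 27 of 28 members with a median of 1.60. Over all genes 2 rose, and 15 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.65e-11, adjusted p = 0.236 with an estimated correlation), and the batch medians were 0.91, 1.66 and 1.87. Inflammatory cytokines had 5 that rose and 8 adjusted over the list alone (median 2.06, camera adjusted p = 1.27e-09, adjusted p = 0.176 with an estimated correlation). DC maturation genes had 3 that rose and 15 adjusted over the list alone (median 1.17, camera adjusted p = 3.69e-08, adjusted p = 0.322 with an estimated correlation). Immediate early genes had 5 that rose, among them Egr2, Ier3 and Egr3, and 12 adjusted over the list alone (camera adjusted p = 3.36e-11, adjusted p = 0.257 with an estimated correlation). Type I interferon response genes did not pass (camera adjusted p = 0.59). They passed as lower in AlloTem without DC only 3 (camera adjusted p = 0.000167) or AlloTem 2 (0.0012). Those fits left the batches unequal between the groups, and the batch medians were -0.79, 0.30 and 0.16.

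T cell transcripts rose in the same libraries. Of 23 T cell markers 8 rose, and 12 adjusted over the list alone, with a median of 1.86 (camera adjusted p = 3.32e-15, adjusted p = 0.176 with an estimated correlation), among them Cd3e by 5.27 ± 0.93 (edgeR adjusted p = 0.024). Cytokines of activated T cells had 3 that rose (Cd40lg, Il21 and Lta) and a median of 3.22; adjusted over the list alone 6 rose and 1 fell (camera adjusted p = 5.19e-07, adjusted p = 0.176 with an estimated correlation). Cd40lg, the T cell ligand that activates DCs through CD40, had 208 counts in AlloTem and 0 in DC only, at least 58.7-fold higher against a floor of 3 counts over the group (edgeR adjusted p = 0.00562). Neutrophil markers and erythroid and platelet markers had medians of 2.00 and 1.30 (camera adjusted p = 0.000833 each, adjusted p = 0.545 and 0.236 with an estimated correlation). Their batch medians were 2.95, 1.23 and 0.37, and 2.50, 1.11 and -0.18. The count of 253 was 420 with the batch block (286 higher, 134 lower) and 98 in the 6 libraries alone. It was 42, 43 and 122 without DC only 1, 2 and 3, and 114 and 92 without AlloTem 1 and 2. Of the 253 genes 34 passed in all 6 such fits, including Ccl17, Cish, Id1, Socs3, Irf4 and Ier3. Il6 did not pass without DC only 1, 2 or 3 or AlloTem 2 (edgeR adjusted p between 0.0541 and 0.0852). Cd274, Lif, Socs1, Lpar6 and Snx22 passed in 1 of the 6 fits each, and Sgk1 in 0.

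SynTem against DC only asked what syngeneic memory T cells add to the culture, and the genes that rose were mostly T cell genes. Of 11 that rose, Cd3e went from 0.101 ± 0.128 to 29.7 ± 18.6 CPM (255-fold, edgeR adjusted p = 0.0161). With 6 counts of Cd3e over the 3 DC only libraries this fold is imprecise, with log2 changes from 7.47 to 9.65 when a library was left out. Cd4, the helper T cell coreceptor that some DCs also express, went from 2.99 ± 0.446 to 25.8 ± 4.01 CPM (log2 3.11 ± 0.36, edgeR adjusted p = 0.0161). Cd3d, Trac, Lat, Bcl11b, Cd3g and Cd27, all expressed by T cells, rose by 6.25, 5.79, 3.96, 6.40, 7.47 and 1.45 (edgeR adjusted p = 0.0161, 0.0161, 0.0161, 0.0212, 0.0328 and 0.0212; that of Cd3g was 0.0727 with the batch block). Nfil3 rose by 1.38 ± 0.21 (edgeR adjusted p = 0.048, 0.063 with the batch block) and Zfp281 by 0.76 ± 0.11 (edgeR adjusted p = 0.0344). The ribonuclease Rnase6 fell by 0.58 ± 0.09 on the log2 scale (edgeR adjusted p = 0.0436). Il1b, Il6 and Tnf differed by -0.18 ± 0.64, 0.49 ± 0.49 and -0.12 ± 0.63 (edgeR adjusted p = 0.967, 0.852 and 0.982). Cd3e (ENSMUSG00000032093) lies on chromosome 9 from 44998740 to 45009627 of GRCm38.

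As lists, T cell markers were higher in SynTem than in DC only for 23 of 23 genes. Of them 6 rose and 22 rose adjusted over the list alone (median 3.22, batch medians 2.07, 2.90 and 4.41, camera adjusted p = 1.28e-37, adjusted p = 0.0911 with an estimated correlation). Interferon gamma response genes were positive for 26 of 28 members with a median of 2.17 (camera adjusted p = 1.82e-19, adjusted p = 0.195 with an estimated correlation). Of these 0 passed over all genes (edgeR; 20 at an unadjusted p under 0.05, 14 by DESeq2, 0 by voom) and 19 rose adjusted over the list alone. Their batch medians were 1.32, 0.47 and 3.67, and the guanylate-binding protein Gbp10 was 8.05 ± 3.06 against 0.27 ± 0.365 CPM (edgeR adjusted p = 0.0552, 0.043 with the batch block). STAT5 response genes had a median of 0.47 with Nfil3 passing and 7 that rose adjusted over the list alone (camera adjusted p = 1.93e-05, adjusted p = 0.195 with an estimated correlation). Inflammatory cytokines and chemokines were higher with camera adjusted p = 0.0224 each (adjusted p = 0.619 each with an estimated correlation), with batch 2 medians of -0.47 and -0.45. Without DC only 3 these values were 0.412 and 0.318, without SynTem 1 0.150 and 0.149, and without SynTem 3 0.0936 and 0.0951. Cholesterol synthesis and oxidative phosphorylation genes were lower, with medians of -0.31 and -0.11 (camera adjusted p = 0.000184 and 0.000259, adjusted p = 0.619 each with an estimated correlation). With the level of Y-linked transcripts as a covariate cholesterol synthesis did not pass (0.0909), and oxidative phosphorylation had a median of 0.06 within batch 3. Markers of plasmacytoid DCs were lower as well, with a median of -0.42 (camera adjusted p = 5.76e-06, adjusted p = 0.195 with an estimated correlation).

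The count of 13 genes in this comparison (11 higher, 2 lower, 1187 at an unadjusted p under 0.05) was 21 with the batch block. It was 0 without DC only 1, without SynTem 2 or without SynTem 3 (edgeR, 799, 1174 and 993 at an unadjusted p under 0.05), 2 without DC only 2 and 56 without SynTem 1. Over the 12 libraries DESeq2 called 254 and limma voom 2. The 2 genes without DC only 2, Rps12-ps3 and Gbp10, and the 2 of limma voom, Cd4 and Trbv3, were named after their values were seen. In the 6 libraries alone 1 gene passed, Cd4 (edgeR adjusted p = 0.0119). Of the 13 genes 0 passed in all 6 fits that left out a library, with the direction kept for 13 of 13. Neutrophil markers were higher with batch medians of 2.26, -0.09 and 2.87 (camera adjusted p = 0.000199, adjusted p = 0.619 with an estimated correlation; 0.112 without SynTem 3). Cytokines of activated T cells had a median of 2.07 (camera adjusted p = 2.03e-05, adjusted p = 0.195 with an estimated correlation). With the block, cell cycle genes (0.023 against 0.0855) and sex-linked transcripts (0.0267 against 0.127) passed too.

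AlloTem was compared directly with LPS to ask how stimulation by T cells differs from stimulation by a bacterial product. Cish rose by 6.38 ± 0.71 and Socs3 by 2.79 ± 0.47 relative to LPS (edgeR adjusted p = 0.00534 and 0.0405, the latter 0.0613 with the batch block). Ccl17, Gprc5c, Irf4 and Ier3 rose by 8.92 ± 0.88, 3.28 ± 0.28, 2.21 ± 0.16 and 2.13 ± 0.27 (edgeR adjusted p = 0.00338, 0.00132, 0.000544 and 0.0107). Osm and the ligand Pdcd1lg2 rose by 3.14 ± 0.45 and 2.80 ± 0.45 (edgeR adjusted p = 0.016 and 0.0289). Sgk1, Bahcc1, the GTPase Rab7b and the cytokine receptor chain Il6st fell by 1.51 ± 0.24, 1.12 ± 0.18, 0.945 ± 0.14 and 0.77 ± 0.12 (edgeR adjusted p = 0.0299, 0.0247, 0.017 and 0.0185). In the 6 fits that left out a library Sgk1 and Bahcc1 passed in 0, and Rab7b and Il6st in 2 each. Il1b, Il6, Tnf and Nfkbiz differed by 0.25 ± 0.64, 1.18 ± 0.47, -0.83 ± 0.63 and -0.94 ± 0.44 (edgeR adjusted p = 1.0, 0.63, 1.0 and 0.8), so no difference in these was detected at this spread.

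In all, 57 genes rose and 8 fell in AlloTem relative to LPS (edgeR quasi-likelihood test, adjusted p under 0.05, 937 at an unadjusted p under 0.05). The count of 65 was 136 with the batch block, 9 in the 6 libraries alone, 36, 9 and 18 without LPS 1, 2 and 3, and 33 without AlloTem 2. Of the 65 genes 8 passed in all 6 fits that left out a library, among them Ccl17, Irf4, Gprc5c and Nfil3. Without LPS 2 Cish, Ier3 and Osm did not pass (edgeR adjusted p = 0.0517, 0.0748 and 0.125), and Socs3 passed only without AlloTem 3. STAT6 response genes were higher with a median of 1.21, 5 that rose and 7 adjusted over the list alone (camera adjusted p = 3.23e-14, adjusted p = 0.0096 with an estimated correlation). Interferon gamma response genes had 27 of 28 positive, a median of 1.85, 1 that rose and 14 adjusted over the list alone (camera adjusted p = 2.2e-20, adjusted p = 0.121 with an estimated correlation). STAT5 response genes had 5 that rose, while adjusted over the list alone 9 rose and 2 fell (camera adjusted p = 9.73e-11, adjusted p = 0.0637 with an estimated correlation). Inflammatory cytokines had a median of 0.99 with Osm passing (camera adjusted p = 0.000177, adjusted p = 0.57 with an estimated correlation). NF-kB targets had a median of -0.09 and did not pass (camera adjusted p = 0.68; 0.0153 without AlloTem 2, lower, and 0.0406 without AlloTem 3, higher). T cell markers were positive for 23 of 23 genes with a median of 1.32, and 10 rose adjusted over the list alone (camera adjusted p = 1.98e-17, adjusted p = 0.137 with an estimated correlation). Cytokines of activated T cells had a median of 1.78 (camera adjusted p = 8.06e-10, adjusted p = 0.0725 with an estimated correlation), with Cd40lg at least 56.3-fold higher against the same floor. Mitochondrial transcripts, kept as a list of RNA quality, were lower in AlloTem for 12 of 13 genes, with a median of -0.16 and batch medians of -0.08, -0.22 and -0.13 (camera adjusted p = 0.00252, adjusted p = 0.752 with an estimated correlation).

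The genes that set AlloTem apart from each of the other 3 groups were sought as the intersection of these tests. Of them 18 rose in all 3 comparisons, including Ccl17, Irf4, Gprc5c, Ier3, Cdh1, Slc30a4, Cldn1, Rnf24, Nfil3 and Pim3, and F630028O10Rik, named after its values were seen, fell in all 3. With the batch block 46 genes rose in all 3. Without SynTem 2 the count of 18 was 3, without LPS 2 it was 6, without LPS 3 and without SynTem 1 it was 8. Without DC only 1 and without DC only 2 it was 9, without SynTem 3 it was 10 and without LPS 1 it was 11.

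Whether the response to alloantigen-specific T cells resembled the LPS response was asked through the fold changes of both comparisons, which share no library. Since 0 genes were called with LPS, 0 calls were shared and 0 were expected (edgeR; with DESeq2 3 genes rose in both, Il1a, Gem and Mir155hg, named after their values were seen). Of the 22 genes that rose in AlloTem over SynTem, 15 were positive with LPS, and their median log2 change with LPS was 0.27. Across all 14413 genes, which are not independent replicates, Pearson's r of the log2 changes was 0.102 and Spearman's rho 0.236; without AlloTem 1 Pearson's r was -0.064, with limma voom 0.207 and at a mean of at least 5 CPM 0.339.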

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

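Chosen only after the results were seen were the tests of T cell carry-over, of an absent LPS response and of the source of SynTem 2.

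In batch 2 the summed level of Y-linked transcripts was 175.07 CPM in SynTem 2 and 0 CPM in the 3 other libraries, and in batch 3 Xist was 455.1 CPM in SynTem 3 against 137.6 to 145.7 CPM in the others. Each library lay far from the 3 others of its batch (gap over range 1.0 and 0.974, above the 95% critical value of Dixon's test for 4 samples). Of 9 such tests 2 passed, and chance flags about 1 in 20 where values vary freely. With 0 CPM in the 3 other libraries of batch 2, any value above 0 in SynTem 2 would give a ratio of 1.0. For the Y-linked transcripts the test therefore decides nothing beyond the values themselves.

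Male T cells carried through the sort do not account for the Y-linked transcripts of SynTem 2. In it 30 markers of conventional DCs stood at a median of 0.99 times the median of the other batch 2 libraries (0.83 to 1.26). Xist stood at 0.35 times the lowest of those libraries. With sex-linked genes left out, the deviations of SynTem 2 correlated at 0.44 with the batch 3 libraries of the other groups and at -0.11 with those of batch 2, which is consistent with DCs of the batch 3 source in this library. DC only 3, cultured without T cells, also held both Xist (145.7 CPM) and Y-linked transcripts (208.62 CPM). Whether the DCs were pooled from several animals or a batch number was misassigned is not given and was not tested. No biological explanation was tested.

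By edgeR 0 genes were called between LPS and DC only, while DESeq2 called 10, among them Cxcl2 and Il1a. By the test set for it, an absent LPS response in the libraries labelled LPS cannot be told apart from a response hidden by the spread. NF-kB targets were higher with camera adjusted p = 1.05e-12 and in 3 of 3 batches, but with an estimated correlation the adjusted p was 0.317. With an estimated correlation 0 lists passed between SynTem and DC only either, so failing that part of the test decides little. With the batch as a block 10 of 26 immediate early genes and 6 of 29 NF-kB targets rose adjusted over their list alone (edgeR). So did 5 of 16 inflammatory cytokines, and 0 members of these lists fell. These rises argue against an absent response for these lists, as far as the batch numbers pair the libraries. Of 26 DC maturation genes 0 rose under the same adjustment. Different DC sources that widen the spread also stay open: with the Y-linked transcript level as a covariate 0 genes were called (968 at an unadjusted p under 0.05), and other differences of source stay in the spread. A weak response after 3 h stays an open biological explanation, as untested.

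The 22 genes higher in AlloTem than in SynTem were weighed against 3 technical explanations. Deeper AlloTem libraries do not account for the difference, since 25 genes were called after thinning each library to the smallest total, including all 24 called before. With the Y-linked transcript level as a covariate 39 genes were called, including 23 of the 24. A difference of DC source that follows these transcripts therefore does not account for the calls as a whole. Other differences of source stay open, and without SynTem 2 only 3 genes were called. Within batches 2 and 3 the median of 23 T cell markers was -2.71 and -2.14, so AlloTem held less RNA of these markers there. This argues against more T cells carried over only if marker levels per T cell were alike in both groups, which was not tested. The batch 2 value also uses SynTem 2, which may hold DCs of another source. Within batch 1 the marker median was 0.12, which decides nothing. Over all libraries it was -1.64, against 2.12 for the genes called higher. Its bootstrap interval (-1.89 to -1.21) was taken over genes and holds no spread between libraries. Activation of the T cells that were carried over stays open and was not tested, as does recognition of alloantigen, which the design names. A difference of T cell strain cannot be told apart from that recognition in this design.

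Other splits of the 6 libraries of each comparison into 3 and 3 were counted, in fits of those 6 libraries alone. With 10 splits a share under 0.05 cannot be reached. Between AlloTem and SynTem 10 of 10 splits called at least as many genes as the real one (0, highest other 601), and between LPS and DC only also 10 (0, highest other 2). Between SynTem and DC only 2 did (real 1, highest other 590), and between AlloTem and DC only and between AlloTem and LPS 1, the real split itself (98 and 9, highest other 0 in both). The splits with 601 and 590 calls point to structure among the samples: they part the libraries with high Y-linked transcripts from the others, and they part 1 of the 3 pairs of the same batch. The real split parts all 3 pairs, and the 3 other splits that do so called 0 genes in each comparison.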

How the results depend on the processing

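The thinning, the Y-linked covariate and the 2 fits without DC only 2 and SynTem 2 were chosen after results were seen. No named gene that passed the test changed sign in another setting, while some that did not pass changed sign, such as Cxcl9 (AlloTem against SynTem, log2 0.18, -0.55 with the batch block). Over all settings the tests of named genes, leaving out list members that did not pass in the 12 libraries, gave the same call in 2441 cases, a weaker one in 453, a stronger one in 19 and a reversed one in 0. For gene lists these numbers were 2602, 152, 161 and 24. RLE and upper quartile scaling changed no count by over 1.5 times. Where values moved, the cause was not tested. Fewer libraries leave less information, and leaving out a library also makes the batches unequal between groups in a fit without the block.

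Genes changed between AlloTem and SynTem (24) were 318 with DESeq2, 41 with no filter, 78 with the batch block, 39 with the Y-linked covariate, 37 with the block and DC only 2 and SynTem 2 left out, 2 with those left out and no block, and 0 in the 6 libraries alone. Between LPS and DC only (0) they were 10 with DESeq2 and 1 with DC only 2 and SynTem 2 left out, with the block and 1 without it. Between AlloTem and DC only (253) they were 676 with DESeq2, 420 with the block, 603 with the covariate, 16 with the 2 libraries left out and 98 in the 6 libraries alone. Between SynTem and DC only (13) they were 254 with DESeq2, 2 with voom, 33 with no filter, 21 with the block, 22 after thinning, 44 with the covariate, 1 with the 2 libraries left out and 1 in the 6 libraries alone. Between AlloTem and LPS (65) they were 288 with DESeq2, 136 with the block, 189 with the covariate, 198 with the block and the 2 libraries left out, 25 without the block and 9 in the 6 libraries alone. Genes higher in AlloTem than in each other group (18) were 110 with DESeq2, 46 with the block, 30 with the covariate and 2 with the 2 libraries left out. Named genes that lost their call with the block, besides those given beside the results, were Cd3g (AlloTem against DC only, 0.0604) and Cpa3 (AlloTem against LPS, 0.0879). Those that gained it were Tnfsf8 (AlloTem against SynTem, 0.0149), Blk (AlloTem against DC only, 0.0286), and Tnfrsf13b and Bcl11b (AlloTem against LPS, 0.0349 and 0.0392). In AlloTem against LPS the TLR signalling list (0.0454) and plasmacytoid DC markers (0.0279) gained it too. The block changed no other call of a named gene or list. The overlap of AlloTem against SynTem with LPS against DC only was 3 with DESeq2, and the correlation of their log2 changes was 0.207 with voom and 0.339 at a mean of at least 5 CPM.

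Lists called with an estimated correlation were 1 between AlloTem and SynTem, 0 between LPS and DC only, 1 between AlloTem and DC only, 0 between SynTem and DC only and 1 between AlloTem and LPS; with fry they were 3, 1, 10, 5 and 5. Between SynTem and DC only (10 lists) 19 passed with the covariate, 18 with the block and the 2 libraries left out and 16 without the block. Lists whose direction turned were, with the Y-linked covariate, type I interferon response (AlloTem against SynTem 7.53e-08, SynTem against DC only 1.07e-08, AlloTem against LPS 0.0305), MHC class I presentation (AlloTem against SynTem 0.0355, SynTem against DC only 0.000681) and DC maturation (SynTem against DC only 0.0326). With the block and the 2 libraries left out they were type I interferon response (6.85e-10 and, against DC only, 0.00043), MHC class I presentation (0.00556), inflammasome (0.0371 and, against DC only, 0.0401) and monocyte markers (0.0425) for SynTem, and NK cell markers for LPS (0.0106) and AlloTem (0.0312) against DC only. With the 2 libraries left out and no block, type I interferon response turned for SynTem against DC only (0.0329).

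Leaving out each library in turn gave 3 to 47 genes between AlloTem and SynTem, 0 to 1 between LPS and DC only, 42 to 323 between AlloTem and DC only, 0 to 56 between SynTem and DC only, 9 to 55 between AlloTem and LPS, and 3 to 23 higher in AlloTem than in each other group. The correlation ranged from -0.064 to 0.151 and the lists called between AlloTem and LPS from 8 to 15. Adjusted p of lists that turned direction ranged, for AlloTem against LPS, from 0.0153 to 0.999 (NF-kB targets), 0.0288 to 0.860 (cell cycle), 0.0290 to 0.999 (cholesterol synthesis) and 0.00283 to 0.999 (type I interferon response). For AlloTem against SynTem they ranged from 0.0127 to 0.572 (cell cycle) and 0.00797 to 0.927 (type I interferon response), and for LPS against DC only from 0.00103 to 0.743 (T cell markers) and 1.1e-05 to 0.495 (type I interferon response).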

Other observations

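Raw counts of some rare cytokines were summed over the 3 libraries of each group, and AlloTem had the deepest libraries. Il21, a cytokine of helper T cells, had 87 counts in AlloTem, 1 in SynTem and 0 in DC only and LPS. It passed against DC only (edgeR adjusted p = 0.0348) and did not against SynTem or LPS (0.124 and 0.0701). Il3 had 66 counts in AlloTem and 0 in each other group. Il4 and Il13 had 93 and 250 counts in AlloTem against 7 and 67 in SynTem (edgeR adjusted p = 0.659 for Il13). Il2 had 22 counts in AlloTem, all in AlloTem 2, 0 in SynTem and LPS and 1 in DC only. Ifnb1 had 14 counts with LPS, 3 in SynTem, 1 in AlloTem and 0 in DC only. These counts were looked up after the other results were seen, and Il2, Il3, Il4 and Ifnb1 were not tested.

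Summed levels of some lists differed between batches within a group. Type I interferon response genes summed to 3055.11 and 3130.09 CPM in DC only 1 and 2 and to 784.58 CPM in DC only 3, and with LPS to 1901.25, 3230.93 and 773.73 CPM. Natural killer cell markers summed to 1113.68 CPM in LPS 1 and 1073.59 CPM in AlloTem 1. Neutrophil markers summed to 1033.34 CPM in SynTem 3. Y-linked transcripts were low but present in SynTem 1 (10.26 CPM) and AlloTem 1 (5.7 CPM).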
